A study of Gallus gallus with 4 samples.

How the data were processed

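The series profiled nuclei of whole chicken eyes at embryonic days 4 and 5 with the 10x Multiome assay, which makes an RNA library and a chromatin accessibility (ATAC) library from the same nuclei. Per the labels, eyes of 3 embryos were pooled for each reaction and about 16000 nuclei were loaded. There were 4 libraries in 4 groups of 1, so no comparison had replicates. Per the submitters' processing notes, Cell Ranger ARC 2.0.2 and the genome build GRCg7b were used; the gene annotation, the settings of the peak calling, any removal of doublets and how the reactions were combined are not given in the sources used here.

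The deposited lists name each barcode and each feature and carry no measured value: 11708 barcodes of 16 bases with suffix 1 or 2, 30108 gene identifiers, of which 14249 had a symbol, and 62595 peaks as sequence, start and end. Peak coordinates are printed as the list gives them, and width is end minus start. Peaks did not overlap each other and had no score. A count matrix and a genome sequence were not used here, so expression, accessibility per nucleus, cell types, sequence motifs and differences between days were not analysed. No columns of per-sample values were left unused.

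Gene positions came from the RefSeq table of the assembly GRCg7b, the same build as the labels name, with 17839 protein-coding genes on chromosomes 1 to 39, Z and W and 23580 when lncRNA genes were added. Of the protein-coding genes, 14300 had a gene name and 3539 only a locus number, and 12747 carried a symbol that the feature list also held. The table has no strand, so the planned promoter window, 1000 bp upstream to 100 bp inside the gene, was applied at both ends of each gene. A gene with a peak overlapping either window by at least 1 bp has an end peak. Gene positions are outer limits over all transcripts, so a start inside those limits is not counted. Peaks within 50 kb are those whose centre lies within 50 kb of a gene end, averaged over both ends. The same peak can count for several genes, also where it lies nearer to another gene.

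Gene lists (19, with 440 symbol entries in all) were written before the data were examined, and symbols were matched exactly; 34 did not match. Each list was compared with 10000 random lists of the same size, matched on chromosome class and on decile of gene density, as a percentile with ties counted at their middle. Values outside percentiles 2.5 to 97.5 were taken to stand apart. These percentiles describe 1 peak list and are not p-values. Unnamed genes had fewer peaks than named genes, so lists drawn from named genes were added after the data were seen. Peaks at gene ends were compared with 100 random placements of the same widths on the same chromosomes, and medians of width carry intervals from 1000 bootstrap resamples of peaks. Chromosome length was taken as the last annotated gene or peak end. The 95% interval of the chromosome ratio came from resampling chromosomes within classes.

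Shared barcodes were compared with the hypergeometric expectation for a pool of 740000 barcodes, the size assumed for the kit. Genes named in the text are, in each list, the 4 with most peaks within 50 kb and up to 4 without an end peak, fewest peaks first. All members of both lens lists may be named, as may the 20 genes with most peaks nearby, 1 per neighbourhood of 100 kb, and the 5 widest peaks. Genes without an end peak are named in full where the list has few, and other genes named were chosen after their values were seen. A few genes that this rule covers are not reported here.

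The list comparison was tested on simulated data for 17839 genes with lists of 20. Of 100 lists without a change, 5 fell outside the range for end peaks and 7 for peaks within 50 kb. The simulation drew the values of each gene independently and took list members from the whole genome. These rates therefore do not cover lists of genes that stand close together and share peaks, such as HOX and erythroid genes. Of 100 lists with the end-peak share lowered by 30 percentage points, 81 were found, and of 100 with 4 added peaks, 77 were found, so smaller shifts in lists of this size can be missed. The alternatives tried were other window sizes, wide peaks only, unmatched lists, nearest-gene assignment, and, added after the data were seen, named genes as background, matching on gene length, 1 gene per 100 kb neighbourhood, symbol synonyms, whole gene bodies and protein-coding genes only. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.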

Results

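Whole eyes of chicken embryos (Gallus gallus) at embryonic day 4 and day 5 were profiled with a droplet assay that reads RNA and accessible chromatin from the same nuclei. The study asks how genes of lens development and of lens disease are regulated. It comprised 4 libraries, 1 RNA and 1 chromatin accessibility library at each of days 4 and 5, each made from the pooled eyes of 3 embryos, so no group had a second replicate. The data analysed here were the nucleus barcodes and the feature list, which held 30108 genes and 62595 accessible peaks in a single list for both days. No counts per nucleus were analysed, so read depth is unknown, and neither RNA levels nor differences between day 4 and day 5 could be measured.

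About 16000 nuclei were loaded per reaction, and 11708 barcodes were listed after the submitters' filtering. Whether doublets, barcodes that hold 2 nuclei, were removed is unknown. The barcode suffix 1 marked 5805 barcodes (exact Poisson 95% interval 5657 to 5956) and suffix 2 marked 5903 (5753 to 6056), intervals that overlap and cover counting error only. These were 36.3% (exact binomial 95% interval 35.5 to 37.0) and 36.9% (36.1 to 37.6) of the nuclei loaded. The binomial intervals take the approximate number loaded as exact, so they too cover counting error only. No label tied a suffix to an embryonic day, so the suffixes were not assigned. The suffixes shared 48 barcode sequences, where independent draws from a pool of 740000 barcodes give 46.3 on average and 34 to 60 in 95% of draws.

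The first comparison asked where in the genome accessible chromatin lay. Peaks gathered at the ends of annotated genes: 23.1% of the 61855 peaks on assembled chromosomes (14302 peaks) overlapped a window from 1000 bp outside to 100 bp inside an end of a protein-coding or lncRNA gene. Random placement of the same widths on the same chromosomes put 8.44% there (8.18 to 8.71% over 100 placements), a 2.74-fold excess. Another 54.1% of peaks lay inside a gene away from its ends, against 62.0% at random, and 22.8% lay between genes, against 29.6%. Peaks were narrow and even in width, with a median of 872 bp and 90% of them between 644 and 924 bp. Peaks at gene ends had a median width of 879 bp (bootstrap 95% interval 878 to 880) and other peaks 870 bp (870 to 871), a difference of a few base pairs that exceeded the sampling error of peaks. The reference used gives no strand, so the start of a gene could not be told from its other end.

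Peak density was higher in the classes of smaller chromosomes. The large macrochromosomes 1 to 5 carried 49.8 peaks per Mb, the intermediate chromosomes 6 to 10 carried 69.8, and the small, gene-rich microchromosomes 11 to 39 carried 93.9. Microchromosomes thus had 1.88 times the density of macrochromosomes (95% interval 1.62 to 2.14 from resampled chromosomes), but 2.62 peaks per protein-coding gene against 4.10. The Z sex chromosome carried 38.4 peaks per Mb and the W sex chromosome 5.82. Single microchromosomes differed widely: chromosomes 35, 38 and 39 had 215, 216 and 214 peaks per Mb, whereas chromosome 33 had 9 peaks for 193 protein-coding genes and chromosome 37 had 0 peaks for 65. Of those genes, 4 on chromosome 33 and 1 on chromosome 37 had a gene name and the others only a locus number.

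**Figure D1:**
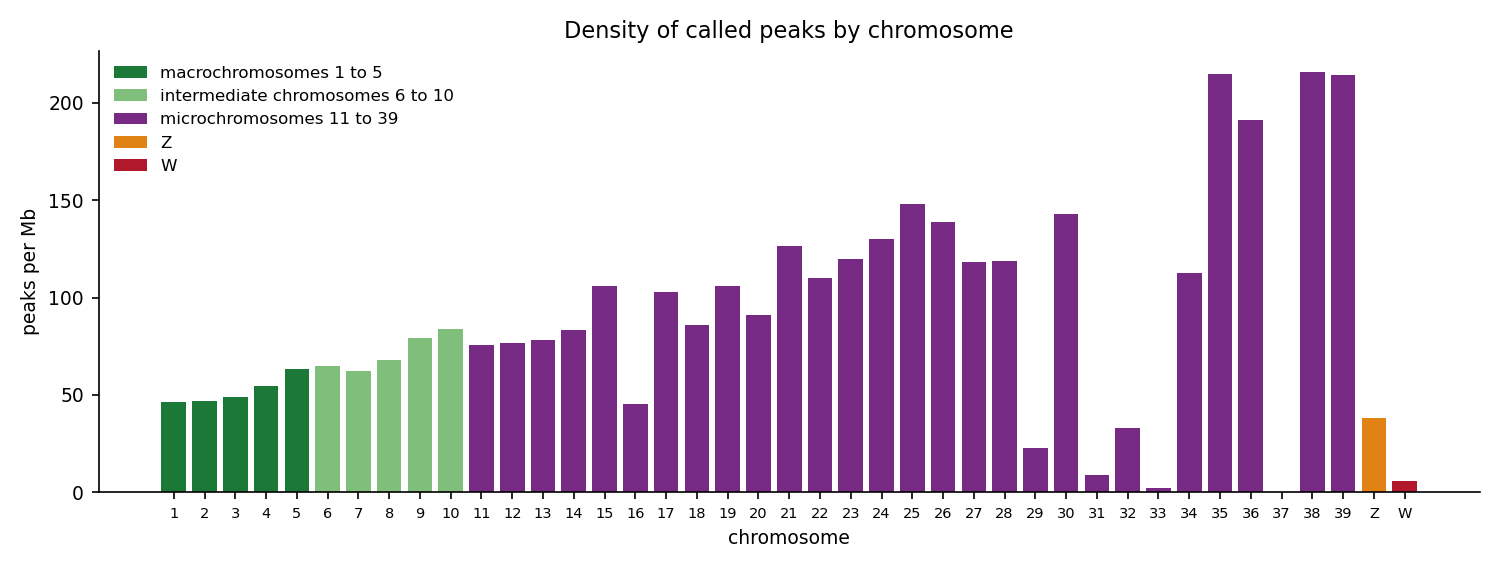
Bars give the number of called peaks per Mb for each chromosome of the GRCg7b build, coloured by chromosome class, with chromosome length taken as the last annotated gene or peak end. Chromosome 1 has 46.2 peaks per Mb and chromosome 38 the most, 216. Chromosomes 16, 29, 31, 32, 33, 37, Z and W lie below chromosome 1, with 45.1, 22.7, 8.96, 32.8, 2.35, 0, 38.4 and 5.82.

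The second comparison asked whether genes of lens fibre cells and of the lens regulatory programme lie in accessible chromatin. Both groups were surrounded by more peaks than matched genes. The 25 measured lens fibre and crystallin genes had a median of 13 peaks within 50 kb of a gene end, against 9 in random lists (percentile 99.8 among 10000 lists). The 22 lens transcription factor genes also had a median of 13, against 6.25, above every random list. Peaks at the gene ends themselves were no more frequent than in matched lists: 17 of 25 lens fibre genes (68.0%, percentile 24.4) and 17 of 22 lens transcription factor genes (77.3%, percentile 56.4) had one.

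Among crystallins, the structural proteins that give the lens its refractive power, the beta-crystallin genes CRYBB3 (chromosome 15, 7000637 to 7002514) and CRYBB2 (7004517 to 7006670) had 21.5 and 20.5 peaks within 50 kb but no peak at either end. CRYAB and HSPB1, which encode small heat shock proteins, had 20.5 and 20 and a peak at 1 or both ends. MIP, the water channel of fibre cell membranes (chromosome 34, 1511032 to 1512968), had 17.5 peaks nearby and a peak at both ends. Most peaks counted near these genes lay nearer to the ends of other genes. CRYBB3 was the nearest gene to 0 peaks, CRYBB2 and MIP to 1 each, and CRYAB and HSPB1 to 2 each. CRYBB1 and CRYBA4 overlap on chromosome 15 and had 13.5 and 13, with end peaks at both genes. CRYAA, the alpha-A crystallin gene (chromosome 1, 109850525 to 109853922), had 13 and a peak at 1 end. By contrast, CRYBB1 was the nearest gene to 20 peaks and CRYAA to 11. At the low end of the list, the gap junction gene GJA3 had 4 peaks nearby and a peak at 1 end. The filensin gene BFSP1, part of the fibre cell cytoskeleton, had 3 and no end peak, and LGSN (chromosome 3, 85407297 to 85424121) had 0 peaks within 50 kb. In all, 8 of the 25 genes lacked an end peak; besides CRYBB3, CRYBB2, BFSP1 and LGSN these were CRYBA2, LCTL, CRYGS and CRYGN.

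The delta-crystallin genes, the main crystallins of bird lenses, stand side by side on chromosome 19. ASL1, delta-1 crystallin, spans 5433498 to 5441253 and had a peak at 1 end. ASL, delta-2 crystallin and the argininosuccinate lyase gene, spans 5420675 to 5429608 and had peaks at both ends. The peak at its lower end, 5419561 to 5420406, lay outside ASL. It overlapped an end of GUSB and an end of CRCP and lay within TPST1, so it cannot be assigned to ASL. The 40.6 kb region around the pair held 9 peaks, which covered 18.0% of it, and 3 other protein-coding genes overlap it, GUSB, TPST1 and CRCP. A peak at 5440220 to 5440787 and another at 5440908 to 5441640 lay inside and across the end of ASL1 away from ASL, and the nearest peak beyond that end lay at 5445712 to 5446651.

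SOX2, a factor needed early in lens and neural induction (chromosome 9, 16567995 to 16570458), had 20 peaks within 50 kb and was the nearest gene to 30 peaks. SIX3 had 17.5, PAX6, a master regulator of eye formation (chromosome 5, 5398323 to 5415898), had 17, and MEIS1, which regulates PAX6 in the lens, had 15.5. SOX1 and SOX3 had 14 each, FOXE3 13.5, and MAF (chromosome 11, 14174786 to 14334814) had 13.5. MAF was the nearest gene to 53 peaks, the most of the list, followed by MEIS1 with 47, where the median protein-coding gene had 2. Fewest peaks lay near MAFA with 4 and EYA1 with 3.5. The 5 genes without an end peak, HSF4, TFAP2A, EYA2, GATA3 and EYA1, each had between 2 and 6 peaks inside the gene, so 22 of 22 had a peak in the gene or within 1000 bp of it.

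The lens fibre result was lost with a 10 kb window (percentile 86.6) or with whole genes and 50 kb on each side (89.0), and the lens transcription factor result with peaks of at least the median width (92.1). Against named genes only, the lens fibre end-peak share of 68.0% stood at percentile 3.62, near the lower limit of the random range.

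**Figure D2:**
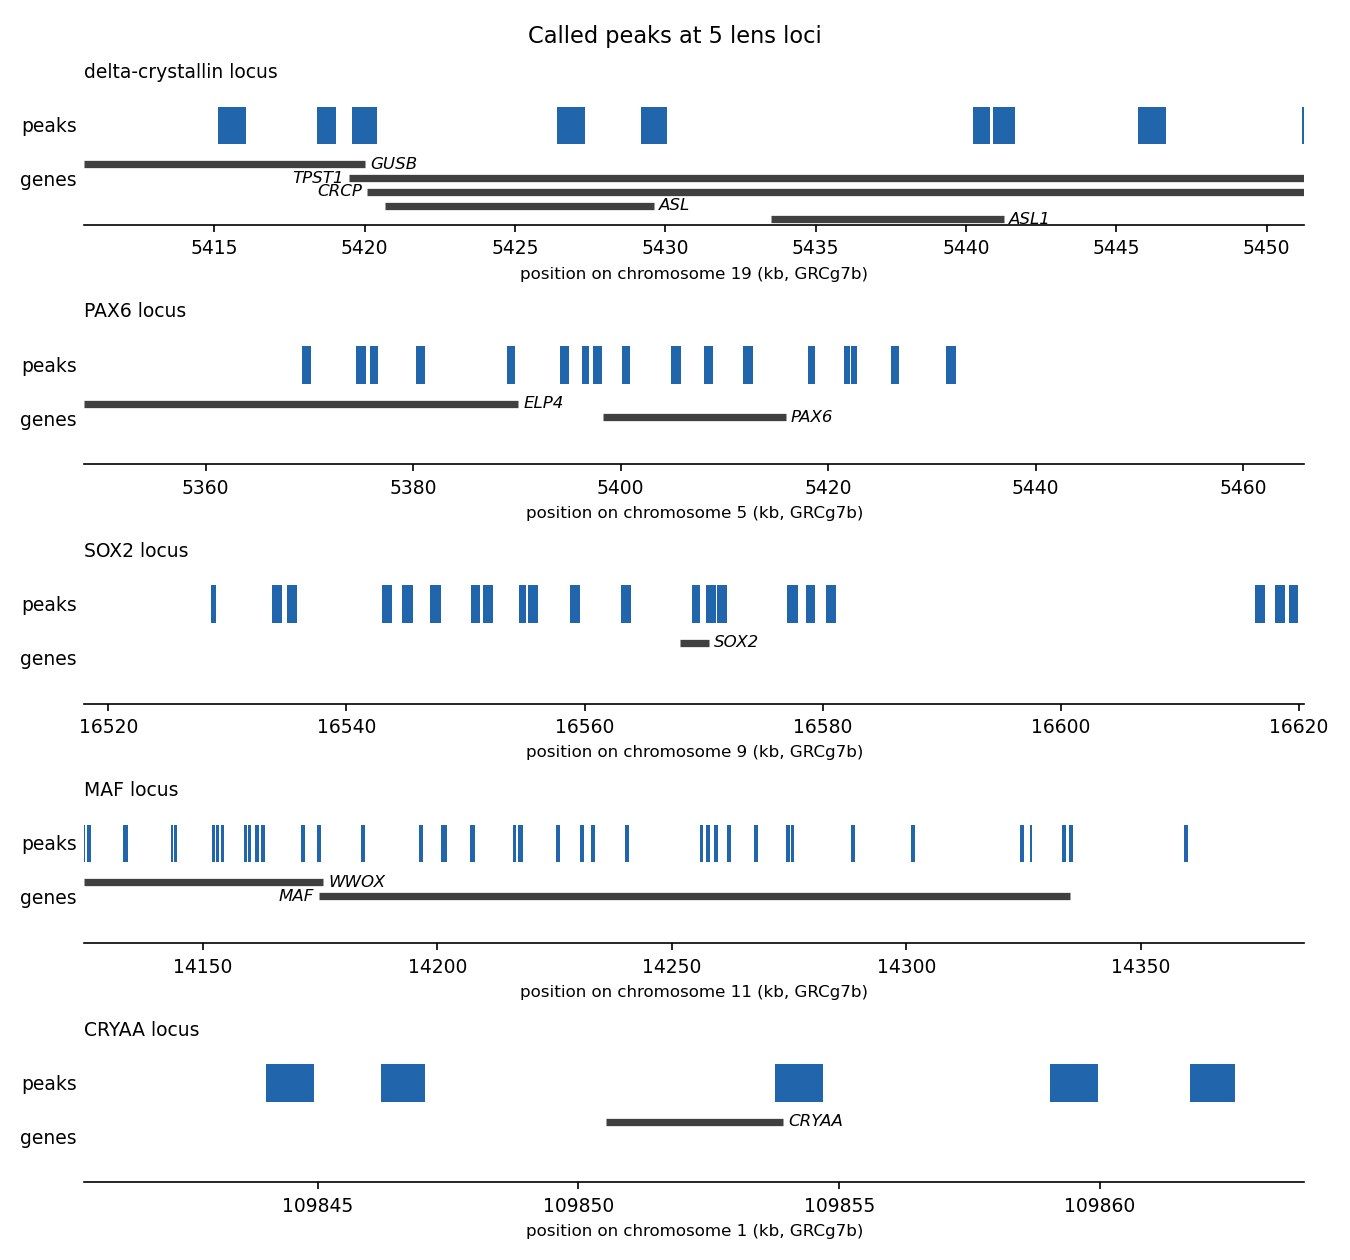
Blue boxes are called peaks and dark bars protein-coding genes, to scale, at 5 lens loci chosen after their values were seen; the horizontal axis is position in kb on the GRCg7b build. Peaks number 9 in the delta-crystallin region, 17 around PAX6, 21 around SOX2, 39 around MAF and 5 around CRYAA.

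Genes mutated in cataract, the clouding of the lens, did not stand apart as a group, in a list written without crystallins. Of 31 measured genes, 26 had an end peak (83.9%, percentile 89.3), and their median of 9 peaks within 50 kb was near the 8.5 of random lists (percentile 68.2). The list shares genes such as MIP (17.5 peaks), LIM2 (14) and BFSP1 (3) with the lens fibre list. OCRL, an inositol phosphatase gene mutated in a syndrome of eye, brain and kidney, had 16.5, and GALT, a galactose metabolism gene, had 15. The 5 cataract genes without an end peak were HSF4, TMEM114, P3H2, CHMP4B and BFSP1, with 13, 10.5, 7, 6.5 and 3 peaks nearby.

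Growth factor signalling genes, which drive lens fibre differentiation, had more peaks around them than matched genes. The 25 genes of the FGF, BMP and MAPK list had a median of 11 peaks within 50 kb against 7 (percentile 99.9), and 20 of 25 had an end peak (80.0%, percentile 69.0). ID1, a BMP target, had 20 peaks nearby, FGF1 19.5, the receptor gene FGFR1 19 and the FGF-responsive factor ETV5 16.5. ID1 was the nearest gene to 2 peaks, FGF1 to 7, FGFR1 to 6 and ETV5 to 3. FGF1 had no peak at an end, nor did FGF8, FGF2, FGFR2 and BMPR1B, with 12, 11, 6.5 and 4 nearby. The result was lost with a 10 kb window (percentile 96.7), with a 200 kb window (84.0) and against unmatched lists (95.5).

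Genes of the neural retina also had more peaks around them than matched genes. The 26 retinal progenitor genes had a median of 13 peaks within 50 kb against 8, above every one of the 10000 random lists, and 23 of 26 had an end peak (88.5%, percentile 94.5). SFRP1, a secreted Wnt antagonist, had 21, the Notch targets HES1 and HES5 had 19.5 and 17, and FOXN4 had 18. SFRP1 was the nearest gene to 11 peaks, HES1 to 12, FOXN4 to 5 and HES5 to 1. The 3 members without an end peak were TBX3, LHX9 and TBX5, and TBX3 held 26 peaks inside the gene. The 30 genes of retinal neurogenesis and neurons had a median of 10.5 against 7 (percentile 99.97), and 26 of 30 had an end peak (86.7%, percentile 92.4). NEUROD4, a neurogenic helix-loop-helix factor, had 24 peaks nearby, LHX1 18.5, the neuronal tubulin gene TUBB3 17.5 and the neurofilament gene NEFL 16. Most peaks counted near these neuronal genes lay nearer to the ends of other genes. NEUROD4 and LHX1 were the nearest gene to 3 peaks each, TUBB3 to 1 and NEFL to 0. OTX2, with 11 peaks nearby, had none at an end, nor did RXRG, STMN2 and CHRNB3. Against unmatched lists the neuronal list fell to percentile 93.9.

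The other cell types of the eye lay closer to matched genes. Of 19 genes of the retinal pigmented epithelium, the pigmented layer behind the retina, 17 had an end peak (89.5%, percentile 95.8), and the median was 8.5 peaks nearby against 7 (percentile 83.8). The melanosome gene PMEL had 19.5, the transporter gene SLC45A2 14 and RLBP1, which binds retinoids, 13. PMEL was the nearest gene to 0 peaks, RLBP1 to 1 and SLC45A2 to 5. RPE65 and TFEC had no end peak. Surface ectoderm and corneal epithelium had end peaks at 13 of 15 genes (86.7%, percentile 92.4) and a median of 10 nearby against 9.5 (percentile 60.3). Its members ranged from 19.5 at KRT14, which was the nearest gene to 1 peak, to 0 at KRT5. Periocular mesenchyme, which surrounds the eye, had end peaks at 13 of 22 genes (59.1%) against 72.7% in random lists (percentile 5.96), or percentile 0.87 against named genes only. When a peak anywhere in the gene or within 1000 bp counted, 20 of the 22 had one, and the list no longer stood apart from length-matched named genes (percentile 42.7). Its members ranged from COL1A1 and PRRX2, with 19 and 18 peaks nearby, to ALX1 and COL3A1, with 2 and 1.5.

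Among the lists for blood vessels and blood cells, the erythroid genes stood apart. Endothelial genes had end peaks at 10 of 16 (62.5%, percentile 15.4) and a median of 10 peaks nearby against 8.25 (percentile 84.8); EGFL7 had 23.5 and the receptor gene TEK 2.5. Of 18 listed erythroid genes, 11 were measured, in 6 neighbourhoods, and GATA1 and KLF1 were among the unmatched. None of the 11 measured erythroid genes had an end peak, against 63.6% in random lists, lower than every random list. With symbol synonyms 8.33% had one, against 66.7%, and with the 2000 bp window 18.2%, against 72.7%. Both shares stayed below the random range. The globin genes HBBA, HBE and HBBR on chromosome 1 had 4.5, 4 and 6 peaks nearby and HBA1 10, whereas SLC4A1, the anion exchanger of red cells, had 18.5 and the blood stem cell factor TAL1 13.5. Macrophage and leukocyte genes had end peaks at 10 of 19 (52.6%, percentile 3.95), or percentile 0.21 against named genes only, and a peak anywhere in the gene at 14 of 19 (percentile 3.90 against length-matched named genes). CD74, FCER1G and IRF8 had 18, 17 and 15 peaks nearby with a peak at 1 end, and the lymphocyte recombinase genes RAG1 and RAG2 had 6 and 3 and no end peak. CD74 was the nearest gene to 2 peaks, FCER1G to 0 and IRF8 to 11.

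The last lists, chosen as a reference, held genes of tissues outside the eye, sensory receptor genes, among them opsin genes of photoreceptors, and housekeeping genes. Liver genes had end peaks at 7 of 23 (30.4%) against 73.9%, below every random list. The fibrinogen genes FGA, FGB and FGG, side by side on chromosome 4, had 3, 4.5 and 3 peaks nearby and APOB had 1, none with an end peak, while the transcription factor gene FOXA2 had 17 and peaks at both ends. Pancreas and gut genes had end peaks at 9 of 16 (56.2%, percentile 5.08), or percentile 0.77 against named genes; the glucagon gene GCG had 2.5 peaks nearby and the mucin gene MUC2 had 1. HOX genes, which pattern the trunk and limbs, had end peaks at 15 of 34 (44.1%) against 73.5% (percentile 0.02), with HOXB13 at 5 peaks nearby and HOXD12 at 14. The HOX result was lost with a 2000 bp window (percentile 7.75). With 1 gene per neighbourhood, which left 6 genes, the share was 33.3% against 66.7%, just inside the limit (percentile 2.56). Skeletal muscle had 10 of 18 (55.6%, percentile 2.80, or 0.40 against named genes), but a peak anywhere in the gene at 16 of 18, the share of length-matched named genes (88.9%, percentile 47.0). Its members ranged from 17.5 peaks near DES to 2.5 near TTN. Sensory receptors had end peaks at 3 of 12 (25%, percentile 0.11). Germline genes had end peaks at 13 of 17 (76.5%, percentile 62.6) and did not stand apart, with 15.5 peaks near SPO11, which cuts DNA in meiosis, and 6 near DDX4. Housekeeping genes had end peaks at 24 of 25 (96.0%, percentile 99.9), all but SNRPD3, and a median of 12 peaks nearby against 9 (percentile 99.2), with 22 at ACTB; the latter result was lost with a 10 kb window (89.5), a 200 kb window (83.9) and nearest-gene assignment (84.2). Against named genes, erythroid, HOX and sensory receptor genes also lay below the random range for peaks within 50 kb (percentiles 0.26, 0.995 and 0.10); against all genes they were low but inside it (6.38, 7.71 and 4.40).

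Taking the 7 lists of eye cell types as 1 set, 126 of 159 genes had an end peak (79.2%), against 28 of 55 genes (50.9%) in the liver, pancreas and gut and germline lists. A gene with an end peak that is on both the retinal neuron and the pancreas and gut lists was counted in the eye set only. The difference of 28.3 percentage points exceeded the 95% range of random pairs of lists, which ran from -12.6 to 13.7 points. This difference reflected low shares in liver (30.4%) and pancreas and gut (56.2%) genes more than a raised share in the eye set. No eye list lay above its random range for end peaks, and all named genes had 82.0%. The germline list, at 76.5%, exceeded the lens fibre (68.0%) and periocular mesenchyme (59.1%) lists. The mean number of peaks within 50 kb was 11 in the eye set and 8.42 in the other, a difference of 2.55 against a random range up to 0.590. The lists were joined into these sets after the data were seen. The percentiles describe this single peak list and are not p-values, because genes are not replicates and no second sample was compared. Over the 19 lists, chance would place 0.950 outside the 95% range if the genes of a list were independent. For end peaks 5 lay outside it, 1 above and 4 below, and 6 lay above it for peaks within 50 kb. Against named genes, 1 lay above and 8 below for end peaks, and 6 above and 3 below for peaks within 50 kb.

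**Figure D3:**
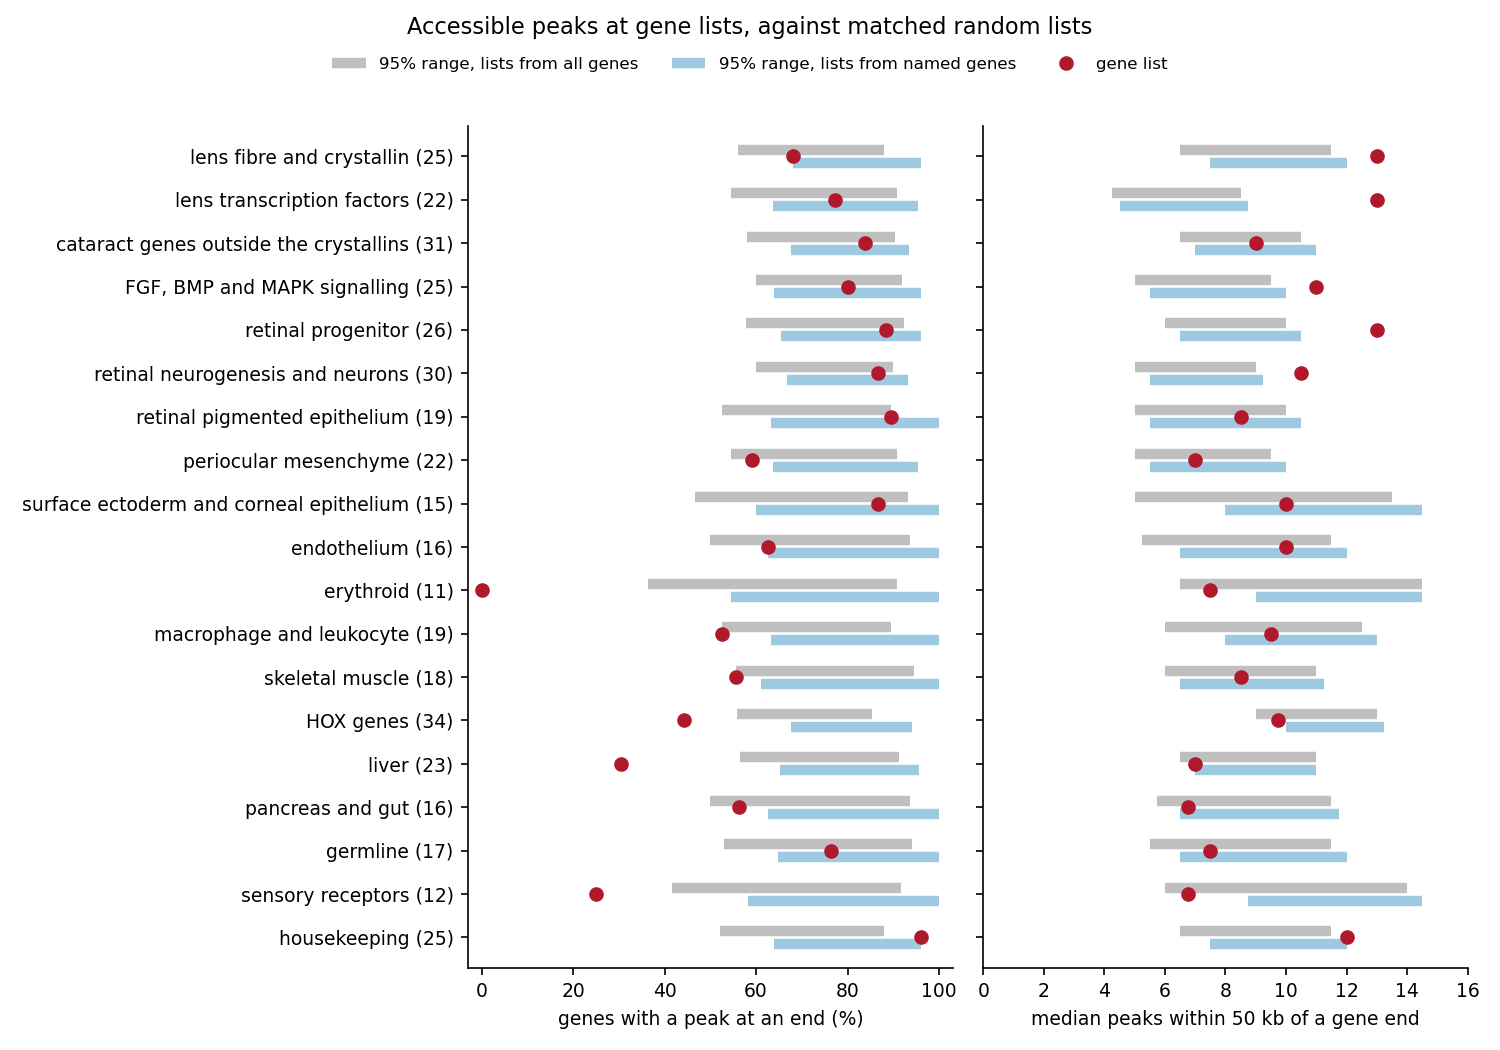
Red points give, for each gene list with its number of measured genes in brackets, the percentage of genes with a peak at an end (left) and the median number of peaks within 50 kb (right); grey and blue bars are the 95% ranges of 10000 matched random lists from all protein-coding genes and from named genes. Erythroid, liver, HOX and sensory receptor lists lie to the left of both ranges for end peaks, at 0, 30.4, 44.1 and 25%, and for peaks within 50 kb lens fibre, lens transcription factor and retinal progenitor lists, each at 13, the FGF, BMP and MAPK list at 11 and retinal neurons at 10.5 lie to the right of both.

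Across all 17839 protein-coding genes, 71.9% had an end peak and the median gene had 8.5 peaks within 50 kb. The densest neighbourhood was a histone gene cluster on chromosome 1, with 39 peaks within 50 kb of HIST1H4B (48157205 to 48157605). Of the 20 densest neighbourhoods, all but HIST1H4B and PCDH8 were on microchromosomes: CD48 and JTB on chromosome 25 had 27 and 26, and PFDN5, ENDOU and ORMDL2 on chromosome 34 had 25.5, 25 and 25. Developmental genes among them were HES4, a Notch pathway repressor on chromosome 21, with 27.5, and PCDH8, a protocadherin gene on chromosome 1, with 25.5. The widest peak, 1452 bp on chromosome 35 (458354 to 459806), overlapped OXA1L, and another of the 5 widest, 1187 bp on chromosome 28 (1561602 to 1562789), lay 682 bp from NFIC.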

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

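A signal in data that no comparison used was the set of 740 peaks on 66 unplaced sequences, 1.18% of all peaks. They carry no position on a chromosome here, and the sequence with most held 73. The tests of regions without signal and of transcription factor genes in other tissues were chosen or divided only after the values were seen. For the other tests, what each explanation predicts was written before their own values were seen. Those tests too were added after the patterns had been seen.

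Genes of the liver, erythroid, pancreas and gut and HOX lists had an end peak less often than matched named genes, with shares from 0 to 56.2%. Against all genes pancreas and gut, with 9 of 16, lay inside the random range (percentile 5.08). Sensory receptors, with 3 of 12, were as low, but their neighbours were not examined. Regions without signal are argued against as the whole cause for the liver list alone: its nearest named genes had end peaks at 15 of 21, a share 41.0 percentage points above the 7 of 23 list genes, where random pairs of lists reached 21.3. For HOX genes the gap was 30.9 points (6 of 8 neighbours, random pairs up to 26.5), but with 1 gene per neighbourhood it was 38.1, equal to the limit of random pairs, and for pancreas and gut it was 10.4 (10 of 15 neighbours, random pairs up to 30.4), so both stay open. The neighbours' own percentiles were 11.7 for liver, 31.5 for HOX and 7.00 for pancreas and gut. For the erythroid list this stays open too, because 3 of 7 neighbours had an end peak (percentile 1.20) while SLC4A1 and TAL1 had 18.5 and 13.5 peaks nearby. Gene length is argued against by length-matched lists of named genes, under which the highest percentile of the 4 lists was 1.18. Transcription starts inside the annotated genes are argued against by counting peaks anywhere in a gene, which left the highest at 0.845 against the same lists. That highest value was HOX, with 70.6% against 85.3%. With the 2000 bp window HOX also had 70.6%, which lay inside the range of lists from all genes (79.4%, percentile 7.75). For HOX the answer thus depends on the background, and starts inside genes stay open. In periocular mesenchyme and skeletal muscle, also low against named genes, the count of peaks anywhere in a gene gave 42.7 and 47.0, so starts inside genes stay open there too. Closed chromatin of these genes in eye nuclei was not tested, since the samples held no other tissue.

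Many peaks lay around genes of the lens fibre, lens transcription factor, retinal progenitor and retinal neuron lists. If this came with transcription factor genes of any tissue, those of liver, gut, muscle, vessels and blood would share it; 27 such genes had a median of 9 peaks within 50 kb, at percentile 78.6. These 27 genes did not stand apart from their random lists. The lens factors and the retinal progenitor list each exceeded them by 4 peaks, where random pairs gave 1.25 and 3 at the upper 95% limit. Retinal neurons exceeded them by 1.5 (limit 1.75). Such gaps cannot decide, because the lists were examined for their high values and random pairs held genes of any kind. The retinal progenitor list also holds genes that are not transcription factors, such as SFRP1. The explanation stays open for the lens factors and both retinal lists. Some groups by symbol, not tissue, lay high: SOX 99.98, NR 99.8 and KLF 98.8. Other such groups of transcription factor genes did not, among them HOX at 0.515, NKX at 51.4, POU at 65.6, TBX at 68.1 and TCF at 78.3. Gene length is argued against by the length-matched percentiles, the lowest of which was 99.2 in the 4 lists. More regulatory elements in use around genes active in the eye was not tested as an explanation, since no second tissue was measured.

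Unnamed predicted genes had an end peak less often than named genes, 31.1% against 82.0%. Small repetitive chromosomes are argued against as the whole cause, because on chromosomes 1 to 5 alone the gap was 46.4 percentage points (95% interval 43.4 to 49.1). Misplaced gene ends are argued against likewise: a peak in or within 10 kb of the gene was found for 96.3% of named and 60.5% of unnamed genes there, a gap of 35.8 points (32.9 to 38.7). Reads shared between gene copies and predicted genes that are never transcribed were not tested and stay open. No biological explanation was tested.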

How the results depend on the processing

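The peak excess at gene ends kept its direction under 6 alternatives, between 1.85 and 3.58-fold, as did the microchromosome ratio, at 1.88 and 1.81. The motif comparisons fixed beforehand were not run. Percentiles that crossed 2.5 or 97.5 follow; the cause was not tested. No list result outside those limits moved to the other side of its random median, but several inside them did, such as end peaks of endothelium (15.4, then 89.0 with the 2000 bp window) and peaks near HOX genes (7.71, then 83.8 against unmatched lists and 86.0 without promoter peaks) and near liver genes (9.88, then 87.2 with whole genes and 50 kb on each side). For end peaks, the 250 bp window gave periocular mesenchyme 1.68, macrophage and leukocyte 0.015 and skeletal muscle 0.55; the 2000 bp window gave HOX 7.75 and pancreas and gut 2.17; peaks of at least the median width gave periocular mesenchyme 0.245, macrophage and leukocyte 0.675 and skeletal muscle 2.32. For peaks within 50 kb, a 10 kb window gave lens fibre 86.6, FGF, BMP and MAPK 96.7, surface ectoderm 99.5 and housekeeping 89.5; a 200 kb window gave FGF, BMP and MAPK 84.0, HOX 1.24 and housekeeping 83.9; nearest-gene assignment gave housekeeping 84.2; wide peaks gave lens transcription factors 92.1 and erythroid 2.15; unmatched lists gave FGF, BMP and MAPK 95.5 and retinal neurons 93.9. Alternatives chosen after seeing the data were as follows. Against named genes, end-peak percentiles were 0.87 for periocular mesenchyme, 0.21 for macrophage and leukocyte, 0.40 for skeletal muscle and 0.77 for pancreas and gut, and with length matched as well 0.80, 0.49, 1.18 and 1.18. With 1 gene per neighbourhood skeletal muscle was at 1.22 and HOX, left with 6 genes, at 2.56; with synonyms pancreas and gut was at 0.975, and with peaks anywhere in the gene, against length-matched named genes, at 0.11. That setting brought periocular mesenchyme to 42.7 and skeletal muscle to 47.0. It left macrophage and leukocyte low at 3.90 (73.7% against 89.5%), just inside the limit, and put surface ectoderm at 21.4 (from 92.4). For peaks within 50 kb, named genes gave erythroid 0.26, HOX 0.995 and sensory receptors 0.10, and with length matched as well 0.825, 0.815 and 0.03, liver 2.40 and pancreas and gut 2.09. Whole genes with 50 kb on each side gave lens fibre 89.0, sensory receptors 2.43 and housekeeping 95.7. No paired analysis was possible because every group had 1 library and the lists hold no value per library. Read depth is unknown, so an absent peak can also reflect too few reads or too few nuclei of a cell type.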

Other observations

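Genes that share the start of their symbol showed a wide spread in end peaks, in 186 groups of at least 10 named genes chosen after the data were seen. The 4 groups with the highest percentiles had end peaks at 48 of 48 EIF genes (translation factors), 41 of 41 RPL genes (ribosomal proteins), 62 of 65 RAB genes (small GTPases) and 33 of 33 VPS genes (vacuolar sorting). In the 5 groups with the lowest shares, 0 of 11 MHCY genes (immune genes of chromosome 16), 2 of 14 MYH genes (myosin heavy chains), 3 of 20 OR genes (odorant receptors), 5 of 14 MMP genes (matrix proteases) and 7 of 20 CLDN genes (claudins of tight junctions) had one. Against named genes, 23 groups lay below percentile 2.5 and 19 above 97.5, where chance gives nominally 4.65 on each side. That count is a rough guide only. Small groups cannot pass 97.5, as COQ with 10 of 10 genes stood at 92.4. Clustered groups are not independent genes: KRT has 21 in 4 neighbourhoods, MHCY 11 in 4 and HOX 35 in 6. For peaks within 50 kb 12 groups lay above 97.5 and 18 below 2.5. Among the 12, SOX genes had a median of 12.5 against 7.5 (percentile 99.98), BCL genes 13 against 8.5 (percentile 99.9) and nuclear receptor (NR) genes 13 against 9 (percentile 99.8). All 28 HIST genes had an end peak and a median of 30.8 peaks nearby, but they fill only 3 neighbourhoods.

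When each peak was given to its nearest gene, FBRSL1 on chromosome 15 took 92, ZFHX3 on chromosome 11 took 90, and CELF4 and ZNF608 on chromosome Z took 81 each, where the 95th percentile of genes was 13. NR2F2, a nuclear receptor gene, took 59 and MAF 53. Many of these genes are long or stand alone, which raises the number by construction.

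The longest stretch without a peak between neighbouring peaks on a chromosome was 9.35 Mb near the end of Z (73874042 to 83222463), which holds 44 protein-coding genes. Of these 5 have a gene name, all ADCY10L copies. The next were 3.73 Mb on chromosome 33, with 189 genes, 4 of them named, and 2.54 and 1.90 Mb on W. No peak lay on the mitochondrial sequence.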
